A study of Mus musculus with 4 samples.

How the data were processed

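H3K27me3 ChIP-seq was done in the mouse glioblastoma line GL261, in control and irradiated cells, with 1 library and 1 input library for each condition. The label IR was read as irradiated, from the title of the series. The dose of radiation and the time of harvest are not given in the sources used here. Per the labels' protocols, cells were fixed with 1% formaldehyde, chromatin was sonicated to fragments of 300 to 500 bp, precipitated with an antibody against H3K27me3 and sequenced in pairs of 150-bp reads on Illumina machines. The submitters' processing notes name BWA, deepTools and the mouse build mm10, without versions. The peak caller, its settings, any filter of duplicate reads and the use of the input libraries are not given in the sources used here. Peaks were listed per library and not on pooled samples.

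The authors deposited 1 peak list for each H3K27me3 library, with the position, the summit and 4 values of each peak. The deposited start, end and summit are other values, positions in bp. The deposited score of a peak was found to be the whole part of 10 times the −log10 p. The deposited ratio is the fold enrichment at the summit over the background that the authors' caller estimated. The deposited −log10 p-value and −log10 q-value of a peak are unadjusted and adjusted over the genome. The largest p in the control list was 0.00495 and in the irradiated list 0.00499, so the authors kept peaks by the unadjusted p, and 3452 control peaks had a −log10 q of 0. Whether these are the final lists of the authors is not given in the sources used here. The fold, p and q are the authors' own values and were used to describe, rank and filter peaks within a list. Lines that gave a further summit of the same interval, 215 in the control list and 679 in the irradiated list, were merged with their peak, and the values at the highest summit were kept.

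The number of reads is not in the lists, and was recovered. Fold and p of a peak followed a Poisson model in which the fold is the scaled pileup plus 1 over the local background plus 1, and the p is the upper tail of the pileup over that background. For 100% of lines in both lists a whole number of ChIP reads and a background were found within a tolerance of 0.01, with more than 1 solution in 0.0794% of control and 0.936% of irradiated lines. The lowest background was 0.918 scaled reads in the control list and 0.704 in the irradiated list, and 1 ChIP read counted as 0.620 and 0.554 scaled reads. In simulated lists of 3178 to 4851 peaks the method returned the right reads and background for 100% of peaks. The ChIP library totals are unknown, so depth is given only as reads per position and relative to the input. The Poisson model is that of a widely used caller, but the labels do not name it.

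Peaks were compared by overlap of at least 1 bp. Chance overlap was described by 100 seeded random placements of the irradiated peaks, between the first and the last annotated gene of each chromosome. Shares have exact (Clopper-Pearson) 95% intervals and ratios of counts have intervals from the binomial share of the summed counts; they cover counting error only. Genes came from a RefSeq table of GRCm38.p6, the assembly of mm10, that gives start and end but neither strand nor transcription start. The design fixed before the data were examined had used promoters, 2000 bp around each transcription start. Since no start could be placed, a gene with 2000 bp on either side was used in place of its promoter, and windows of 500 and 5000 bp as alternatives. Exons and introns were not resolved. Random placements for the share of peaks in genes numbered 20. No genome sequence was given, so base composition of peaks, repeats and CpG-matched random lists were not computed. Long genes have more room for peaks in this measure, so random lists matched on length decile and chromosome were added beside those of equal size, 10000 of each.

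The 22 gene lists were fixed before the data were examined, and 755 of 765 entries matched a protein-coding gene. Genes named in the text followed a rule fixed at the same time. It took the 10 genes with a peak in the irradiated list alone, the 10 in the control list alone and the 10 in both with the lowest q (in both, by the weaker of the lists), ties being settled by p, fold and name. Predicted genes (Gm and Rik names) were left out, and genes of a class with the same strongest peaks counted once. From each fixed list up to 4 marked members with the lowest q were taken. Some genes that the rule took are not reported here. Genes and regions outside the rule are said to have been chosen after their values were seen; the other members of short lists are named to complete a count of few genes.

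Alternatives fixed beforehand were a −log10 q of at least 5, equal numbers of peaks, merging of peaks within 1000 or 5000 bp, other definitions of overlap, other windows, peaks without unplaced scaffolds and the Y chromosome, and low-fold peaks for the background. Alternatives added after seeing the data were a q of at most 0.05, a −log10 p of at least 5, peaks of at least 12 reads, gene ends in place of whole genes, matched random lists and peaks moved by up to 500 kb. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots matplotlib 3.10.9.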

Results

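H3K27me3, the trimethylation of lysine 27 of histone H3 that Polycomb repressive complexes deposit on silent genes, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in GL261, a mouse glioblastoma cell line. The series compared untreated with irradiated cells to ask where the mark lay on the chromosomes after radiation. It held 4 libraries: H3K27me3 from control cells, H3K27me3 from irradiated cells, and an input library (DNA without immunoprecipitation) for each condition. The lists of enriched regions (peaks) of the 2 H3K27me3 libraries were analysed; the input libraries were not analysed here by themselves. With 1 library per group there were no replicates, so no difference between the lists could be set against replicate error, no p-value between conditions was computed, and every interval given covers counting error only.

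The control list held 9866 peaks and the irradiated list 16091, a ratio of 1.63. The peaks were narrow, with a median width of 357 bp in the control list and 364 bp in the irradiated list, and covered 4.04 Mb and 6.87 Mb of the mm10 genome, a ratio of 1.70. The authors' fold enrichment at the summit had a median of 3.43 (quartiles 3.02 and 3.75) in the control list and 3.67 (quartiles 3.19 and 4.16) in the irradiated list. Most peaks were weak: 675 control peaks (6.84%) and 2453 irradiated peaks (15.2%) had a q of at most 0.05, and on those peaks the ratio between the lists was 3.63. This q lay at a −log10 p of 5.53 in the control list and 5.08 in the irradiated list; at a −log10 p of at least 5 in both, 1096 control and 4412 irradiated peaks remained, a ratio of 4.03. From the fold and p of each peak, the median number of ChIP reads at a summit was 10 in the control list (quartiles 8 and 11) and 11 in the irradiated list (quartiles 10 and 13). At the lowest background, a peak needed 7 reads in the control list and 8 in the irradiated list. The recovered average was 1.48 ChIP reads per position in the control library and 1.27 in the irradiated library. This average also depends on the fragment length that the caller used. The depth of the input was 62.0% and 55.4% of that of its ChIP library, if the caller scaled ChIP to input.

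In both libraries the peaks were concentrated on chromosomes 15, 6 and 11. Chromosome 15, with 3.84% of the span between first and last annotated genes, held 2302 control peaks (23.3%, 95% exact interval 22.5 to 24.2) and 2897 irradiated peaks (18.0%, 17.4 to 18.6). Chromosome 6 held 1251 (12.7%) and 1983 (12.3%), and chromosome 11 held 925 (9.38%, 8.81 to 9.97) and 2165 (13.5%, 12.9 to 14). The 12 genes with the most peaks, chosen after their values were seen, all lay on these chromosomes. Ano2, a calcium-activated chloride channel gene on chromosome 6 (125690419 to 126040133), held 35 control and 68 irradiated peaks. Col22a1, a collagen gene on chromosome 15 (71795795 to 72150979), held 40 and 63, and Tg, which encodes thyroglobulin, the thyroid hormone precursor (chromosome 15, 66670754 to 66850721), held 47 and 52. On chromosome 11, Dock2, which encodes a Rac activator of leukocytes, held 26 and 47, and Tenm2, which encodes a teneurin of neuronal synapses, held 16 and 34. Among peaks with a q of at most 1e-05 the concentration was reduced, with 1.48% of 135 control peaks and 6.57% of 198 irradiated peaks on chromosome 15.

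**Figure D1:**
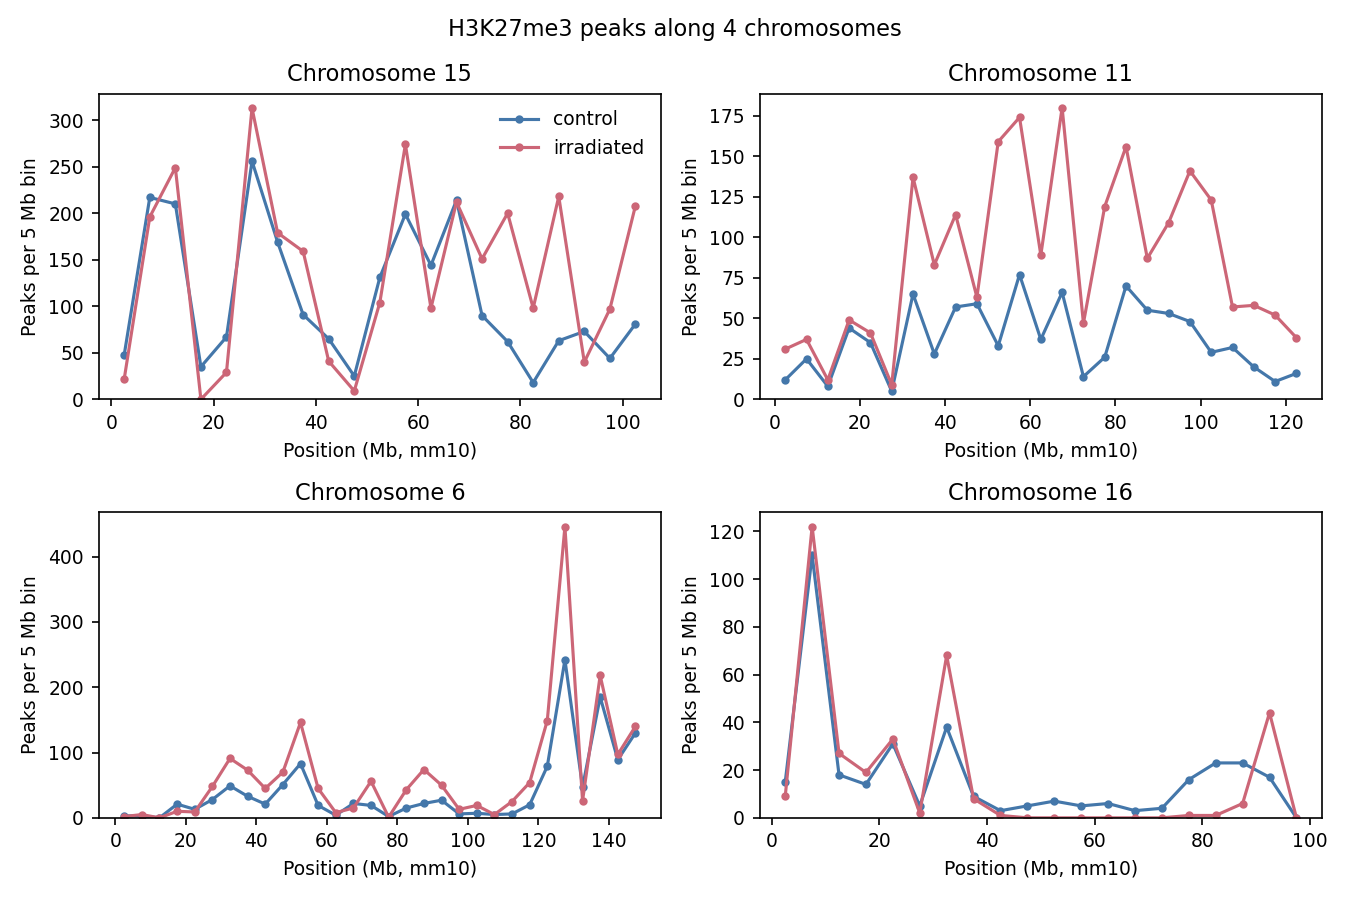
H3K27me3 peaks per 5 Mb bin (vertical axis) against position in Mb on chromosomes 15, 11, 6 and 16 (horizontal axis) for the control library (blue) and the irradiated library (red), 1 library each. On chromosome 16 between 45 and 90 Mb there were 92 control and 8 irradiated peaks.

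The irradiated list was longer on 18 of the 19 autosomes, and beyond counting error on 16 of them. The ratio of irradiated to control peaks was highest on chromosome 9, at 2.48 (2.15 to 2.86), followed by chromosome 11, at 2.34 (2.17 to 2.53). It was 1.26 (1.19 to 1.33) on chromosome 15, 0.969 (0.832 to 1.13) on chromosome 16 and 0.996 (0.841 to 1.18) on the X chromosome. Peak numbers in 5 Mb bins of the autosomes followed each other between the lists, with a Spearman correlation of 0.865 across 502 bins, which are not independent replicates. Between 45 and 90 Mb of chromosome 16 the order of the lists turned, with 92 control peaks and 8 irradiated peaks. The irradiated share there was 8.00% (3.52 to 15.2) against 62.0% in the whole genome. Between 15 and 20 Mb of chromosome 15 there were 35 control peaks and 0 irradiated peaks. Among bins with at least 30 peaks of both lists together, the reverse extreme was 25 to 30 Mb of chromosome 17, with 1 control and 29 irradiated peaks. These bins were picked after their values were seen.

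**Figure D2:**
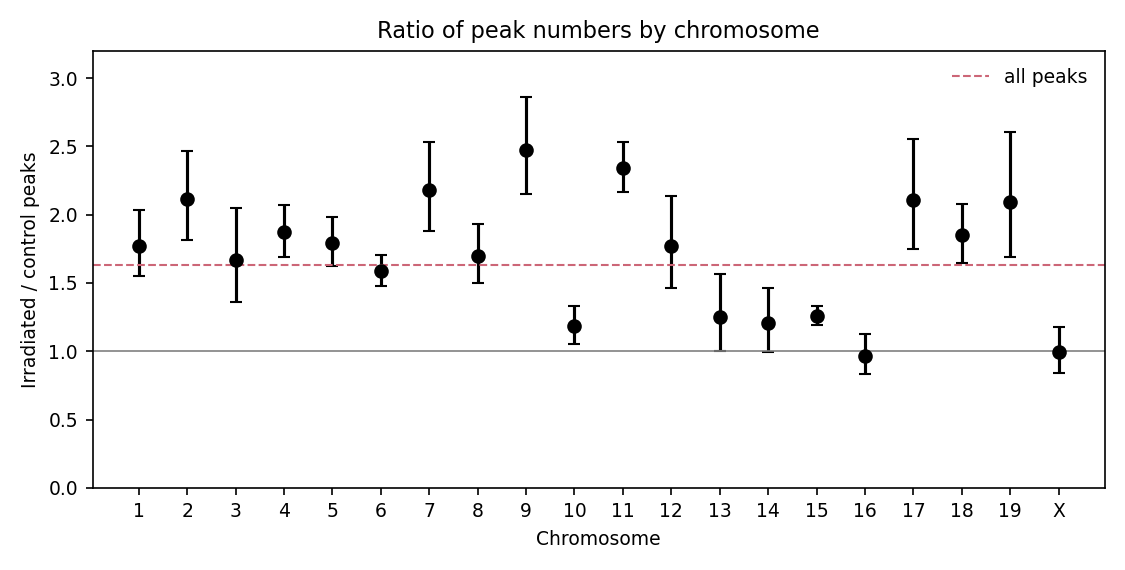
Ratio of irradiated to control H3K27me3 peak numbers (vertical axis) for each chromosome (horizontal axis). Points are ratios, bars are 95% intervals of counting error, the grey line marks equal numbers and the dashed line the ratio of all peaks, 1.63; chromosomes 9 and 11 lie highest, at 2.48 and 2.34.

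Of the control peaks, 2108 (21.4%, 20.6 to 22.2) overlapped an irradiated peak by at least 1 bp, and of the irradiated peaks 2136 (13.3%, 12.8 to 13.8) overlapped a control peak. Irradiated peaks placed at random within their chromosomes met a median of 107 control peaks, so the observed overlap was 19.7 times as large, and 7.78 times as large when each peak was moved by at most 500 kb. Sharing was more frequent among stronger peaks. Control peaks with a q above 0.05 were shared in 18.6% of cases (17.8 to 19.4), those with a q of at most 1e-05 in 92.6% (86.8 to 96.4). The same shares of the irradiated list were 10.3% (9.83 to 10.9) and 80.8% (74.6 to 86.0). Of the peaks with a q of at most 1e-05, 50 of 135 control and 72 of 198 irradiated ones lay between 30 and 35 Mb of the X chromosome. Another 34 and 43 lay between 14 and 16 Mb of chromosome 5. Among peaks of this q, 75.6% and 50.5% had an input background at least 1.5 times the lowest. Whether their sharing comes from the mark or from raised input was not tested. In 1932 pairs of peaks that overlapped 1 to 1, the irradiated fold was a median of 1.14 times the control fold (quartiles 0.953 and 1.36), and it was the higher one in 1344 pairs (69.6%). These folds belong to 2 lists that were scaled separately, and the lowest fold called at the lowest background was 2.78 in the control list and 3.19 in the irradiated list, a ratio of 1.14. In 236 pairs with both q at most 0.05 the median fold ratio was 1.11, and in 77 with both at most 1e-05 it was 1.12. With a reciprocal overlap of 50% the shared part came to 12% of control and 7.38% of irradiated peaks.

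**Figure D3:**
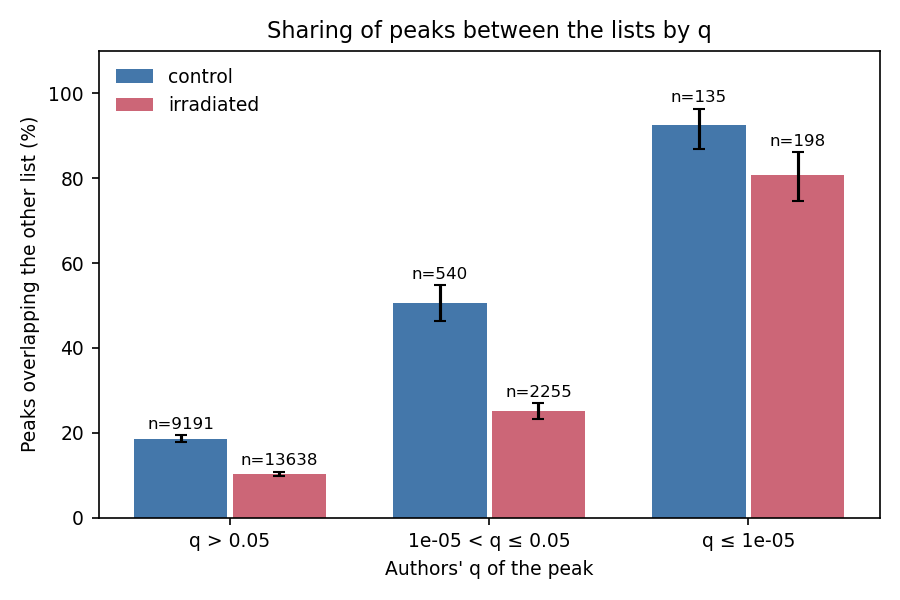
Share of peaks that overlapped a peak of the other list, in percent (vertical axis), by the authors' q of the peak (horizontal axis), for the control (blue) and irradiated (red) lists. Bars are shares, error bars are 95% exact binomial intervals of counting error, and n is the number of peaks. Sharing in the control list goes from 18.6% to 92.6%. Many peaks with a q of at most 1e-05 lay over a raised input background.

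Genes were taken as marked when a peak of any strength lay in the gene or within 2000 bp of it. Since peaks reached down to an unadjusted p of 0.00495 in the control list and 0.00499 in the irradiated list, and most rested on few reads, a marked gene is one with a listed peak and not one with a domain of H3K27me3. Of 21887 protein-coding genes, 803 had a peak in both lists, 522 in the control list without one in the irradiated list, and 991 in the irradiated list without one in the control list. Independent lists of these lengths would share 109 genes, and 236 if drawn within classes of gene length and chromosome; a gene in both lists can hold different peaks in each. The share of peaks in such gene regions lay below that of random placements: 31.9% of control peaks (31.0 to 32.8) against 42.9%, and 38.1% of irradiated peaks (37.3 to 38.8) against 43.9%. Outside any annotated gene lay 52.7% of control peaks and 46.9% of irradiated peaks. When peaks with a q of at most 0.05 were used, 80 genes had a peak in both lists, 33 in the control list alone and 375 in the irradiated list alone; at a −log10 p of at least 5 the numbers were 129, 59 and 588. With equal numbers of peaks from each list the order turned, with 680 genes in both lists, 645 in the control list alone and 599 in the irradiated list alone.

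Genes with a peak in the irradiated list and none in the control list were led by Apol11a, a gene of the apolipoprotein L family on chromosome 15 (77508129 to 77517874). Its strongest peak, at 77510660 to 77511298, had 19 reads, a fold of 6.76 and a q of 1.47e-05. Apol11b, a neighbour of the same family (77633951 to 77643286), held 6 irradiated peaks, the strongest with a fold of 5.46 and a q of 0.00171. Pnoc, which encodes the precursor of the neuropeptide nociceptin (chromosome 14, 65400673 to 65425564), had a peak at 65423450 to 65423740 with a fold of 5.91 and a q of 7.81e-05. Chrna5, which encodes a nicotinic acetylcholine receptor subunit (chromosome 9), had a fold of 5.79, and Kcnmb2, which encodes a subunit of calcium-activated potassium channels (chromosome 3), a fold of 5.46, both with a q of 0.00171. Zpbp2, a gene of sperm binding to the egg coat (chromosome 11), had a q of 0.000813 for a peak just outside the gene. Jaml, which encodes a leukocyte adhesion molecule (chromosome 9), held 6 peaks with a lowest q of 0.00171. Frmpd1, which encodes a scaffold protein with FERM and PDZ domains (chromosome 4), held 10 peaks with a lowest q of 0.000659. Tmem217 on chromosome 17 and Gsg1l2 on chromosome 11 completed the list, with lowest q of 0.000282 and 0.00171. A gene without a peak in the control list may still carry the mark below the calling threshold there. With a window of 5000 bp, Frmpd1 and Apol11b had a peak in both lists.

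Genes with a peak in the control list and none in the irradiated list each held 1 control peak among those named. Coro2a, which encodes an actin-binding coronin (chromosome 4, 46536937 to 46601929), had a peak at 46582834 to 46583131 with a q of 1.05e-10, but over an input background of 9.66 scaled reads, against 0.918 at the lowest background of this list. Elobl (chromosome 11) had a q of 7.74e-05, also over a raised background, of 3.18 scaled reads. The vomeronasal receptor gene Vmn2r129 and the zinc finger gene Zfp991, both on chromosome 4, had a q of 0.00198, with folds of 5.69 and 5.37. Zfp991 lies within the span of Zfp978, which had a peak in both lists, so the Zfp991 peak is also counted for Zfp978. Vmn2r115, another vomeronasal receptor gene (chromosome 17), and Scml4, a relative of the Polycomb group gene Scm (chromosome 10), had a q of 0.0157. Bend6, a BEN domain gene (chromosome 1), had a q of 0.0236. Dnah2, which encodes an axonemal dynein (chromosome 11), and Arhgap22, which encodes a GTPase activator (chromosome 14), did not reach a q of 0.05, with 0.0519 and 0.0823. With a window of 5000 bp, Elobl and Scml4 had a peak in both lists.

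Genes marked in both lists at the lowest q included members of repeated gene families and a group on chromosome 15. Sfi1, which encodes a centrin-binding centrosome protein (chromosome 11, 3131850 to 3203347), held 8 control and 7 irradiated peaks, with lowest q of 5.01e-16 and 6.52e-13. The control peak had a fold of 4.88 over a raised input background of 10 scaled reads and lay at another site than the irradiated one. Spin2f, of the spindlin family on the X chromosome, had folds of 6.85 and 8.45. Speer4e and Speer4c, of a rodent family expressed in the testis (chromosome 5), had control folds of 6.51 and 4.43 and irradiated folds of 7.41 and 14.6, at different sites of the gene in each list and, for Speer4c, over a control background of 3 scaled reads against 0.704 in the irradiated list. Zfp978, which shares its peak with Zfp988 (chromosome 4), and Sp110, which shares its peak with Sp140, another nuclear body gene of the immune system (chromosome 1), had 8 and 5 control peaks and 4 and 3 irradiated peaks. On chromosome 15, Lifr, the receptor gene for leukemia inhibitory factor (7090610 to 7197489), held 6 control and 14 irradiated peaks. Its neighbour Egflam, which encodes the retinal matrix protein pikachurin (7206120 to 7398744), held 29 and 37, Pdzd2, a PDZ domain gene (12359711 to 12739968), held 28 and 49, and Marchf11, a ubiquitin ligase gene (26309048 to 26409586), held 15 and 13. The lowest q of Lifr was 0.000106 in the control list and 7.68e-07 in the irradiated list, and that of Pdzd2 was 0.000438 and 1.12e-06. For both genes these peaks lay at different sites in the 2 lists. The backgrounds differed too, with 1.90 and 0.864 scaled reads for Lifr and 1.25 and 0.704 for Pdzd2 in the control and irradiated list.

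Among the 22 gene lists fixed beforehand, the ligands of the Wnt, Bmp, Fgf and Hedgehog pathways, which direct embryonic patterning, lay above the 99th percentile of random lists in both libraries. Of 41 genes, 8 had a control peak and 10 an irradiated peak, with 7 in both, at the 99.8th and 99.9th percentile of 10000 random lists of the same size, and at the 99.6th and 99.8th when random genes were matched on length and chromosome. Bmp6 (chromosome 13) and Wnt6 (chromosome 1) had irradiated folds of 4.81 with a q of 0.0119, and control folds of 3.11 with a q of 1 and 3.75 with a q of 0.385. Bmp3 (chromosome 5) had folds of 2.67 in the control and 4.16 in the irradiated list, and Wnt2 (chromosome 6) folds of 2.81 and 4.10; both had a control q of 1 and an irradiated q of 0.0536. A fold given per list is that of the strongest peak of the gene in that list, which for Bmp6, Wnt6, Bmp3 and Wnt2 lay at different sites in the 2 lists. With peaks of a q of at most 0.05, 0 control and 2 irradiated members of this list were left, and with gene ends in place of whole genes 2 and 1. Markers of microglia, macrophages and leukocytes had 1 marked member of 25 in the control list and 6 in the irradiated list (38.6th and 99.1st percentile, matched 58.3rd and 99.8th). Cd4, the T cell coreceptor gene (chromosome 6), was marked in both lists, with 1 control peak of a fold of 2.40 and 7 irradiated peaks. The strongest irradiated one, at another site than the control peak, had a fold of 5.14 and a q of 0.00261. The integrin gene Itgam (chromosome 7) and Csf1r, the receptor gene for colony stimulating factor (chromosome 18), had irradiated folds of 4.16 and 3.63, with q of 0.0536 and 0.0788, and no control peak. With peaks of a q of at most 0.05, 0 control and 1 irradiated member of this list were left, and with gene ends 1 and 2.

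Neuron markers had 2 and 5 marked members of 25 (68.2nd and 96.8th percentile, matched 39.1st and 92.7th). Grin2b, which encodes an NMDA receptor subunit (chromosome 6, 135713221 to 136173615), held 41 control and 35 irradiated peaks, and Celf4, which encodes a neuronal RNA-binding protein (chromosome 18, 25477620 to 25754520), held 6 and 22. Rbfox3, which encodes the neuronal nuclear antigen NeuN (chromosome 11), and Camk2a, a synaptic kinase gene (chromosome 18), had irradiated folds of 3.73 and 2.94 and no control peak. Mesenchymal, fibroblast and endothelial markers had 5 marked members of 26 in each list (98.9th and 96.2nd percentile, matched 87.2nd and 83.2nd). Vwf, which encodes von Willebrand factor (chromosome 6, 125552948 to 125686679), held 19 irradiated peaks and no control peak. The strongest lay outside the gene, between Vwf and Ano2 and within 2000 bp of each. The 5 Mb bin from 125 to 130 Mb held 242 control and 446 irradiated peaks. Kdr, the receptor gene for vascular endothelial growth factor (chromosome 5), held 1 control and 4 irradiated peaks, and the endothelial adhesion gene Pecam1 (chromosome 11) and the E-cadherin gene Cdh1 (chromosome 8) were marked in both lists. The protocadherin clusters had 14 marked members of 57 in the control list and 0 in the irradiated list, but all 14 are Pcdha genes that overlap on chromosome 18 and share 2 control peaks, the strongest at 37158866 to 37159223 with a fold of 3.60 and a q of 0.385. With peaks of a q of at most 0.05, neuron markers had 1 control and 2 irradiated members left, and mesenchymal, fibroblast and endothelial markers 0 and 1; with gene ends the numbers were 0 and 0, and 1 and 2. With equal numbers of peaks each of these lists had 3 irradiated members.

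No member of the Polycomb and H3K27 enzymes (37 genes), the cell cycle drivers (33), the interferon response and nucleic acid sensing genes (33) or the oligodendrocyte markers (17) had a peak in either list. Their irradiated counts lay at the 2.20th, 2.95th, 2.95th and 11.6th percentile of random lists, and their control counts at the 4.74th, 6.28th, 6.28th and 17.6th. With random genes matched on length and chromosome these were the 0.66th, 3.8th, 7.49th and 12.1st in the irradiated list and the 3.17th, 12.2nd, 17.2nd and 16.3rd in the control list. Housekeeping genes had 1 control member of 40 (Ywhaz) and 0 irradiated members (19th and 1.65th percentile, matched 42.3rd and 3.27th). DNA repair and damage signalling genes had 1 member of 44 in each list, Brca1 in the control list (fold 2.96) and Mgmt, which encodes the enzyme that removes alkyl groups from guanine, in the irradiated list (fold 4.05, q 0.0536), at the 15.3rd and 6.45th percentile (matched 8.53rd and 1.84th). Of 30 p53 target genes, Perp was marked in both lists and Tigar in the irradiated list (30.6th and 41.2nd percentile, matched 54.7th and 60.8th). Cell cycle inhibitors and senescence genes had 1 marked member of 18 in each list, Il6 and Igfbp7 (51.9th and 38.5th percentile, matched 58.1st and 39.3rd).

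The classical Polycomb targets stayed within the range of random lists. The peak lists thus did not single out the genes where this mark would be looked for first. That limits what any gene called marked here says about H3K27me3. Of 81 developmental transcription factors, 3 had a control peak and 6 an irradiated peak (19.5th and 41.6th percentile, matched 44.6th and 63.9th). Pax2, a kidney and midbrain regulator (chromosome 19, 44746601 to 44838269), held 2 control and 10 irradiated peaks, the strongest irradiated one with a fold of 4.78 and a q of 0.0107, while Lmx1a and Gata5 had irradiated folds of 4.49 and 3.38 and Six2 a control fold of 4.08. Of 39 Hox cluster genes, 1 and 3 were marked (matched 36.6th and 47.8th percentile). Hoxc4 (chromosome 15) had a control fold of 4.59 and an irradiated fold of 4.22, at different sites, and Hoxb3 and Hoxc5 had irradiated folds of 3.02 and 2.87. The Hoxc5 peak lay outside Hoxc5 and inside its neighbour Hoxc4, so it is also counted for Hoxc4. Glioma stem and receptor genes had 3 marked members of 43 in each list. Egfr, the epidermal growth factor receptor gene (chromosome 11), held 4 control and 7 irradiated peaks, Prom1 (chromosome 5), which encodes the stem cell antigen CD133, 3 and 5, Fgfr2 had a control peak and Chil1 an irradiated peak. Of 14 astrocyte markers, the glutamate transporter gene Slc1a2 (chromosome 2) and the bicarbonate transporter gene Slc4a4 (chromosome 5) were marked in both lists. The matched percentiles were the 51.1st and 31.5th for glioma stem and receptor genes and the 73.6th and 60.4th for astrocyte markers.

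Chemokines and cytokines had 3 marked members of 38 in the control list (Il6, Ccl4, Ccl22) and 1 in the irradiated list (Ccl4), but 1 and 1 with a window of 500 bp and 5 and 4 with one of 5000 bp. The main counts lay at the 70.2nd and 10.2nd percentile (matched 86.5th and 14th). Antigen presentation and immune checkpoint ligands had 3 control members of 29 (Ulbp1, Cd86, Nt5e) and 1 irradiated member (Ciita, the activator of class II antigen presentation), at the 82.4th and 18.5th percentile (matched 92nd and 35.4th). Imprinted genes had 1 member of 26 in both lists, Slc38a4 (chromosome 15) with 4 peaks in each. Of 24 cancer-testis and germline genes, Mov10l1 (chromosome 15), a gene of the piRNA pathway, held 1 control and 15 irradiated peaks, Asz1 a control peak and Dnmt3l an irradiated peak. Genes specific to other organs had 0 and 3 marked members of 32, the keratin gene Krt1, the pluripotency gene Nanog and the cardiac myosin gene Myh6. With a window of 5000 bp the numbers were 0 and 7. The matched percentiles in the control and irradiated list were the 17.6th and 9.27th for imprinted genes. They were the 74.7th and 59.1st for cancer-testis and germline genes, and the 20.6th and 88.5th for genes specific to other organs. By chance, 1.1 of the 22 lists would lie above the 95th percentile in each library, and 3 control and 4 irradiated lists did. With random lists matched on length and chromosome there were 1 and 2, and with peaks of a q of at most 0.05 there were 0 and 0.

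**Figure D4:**
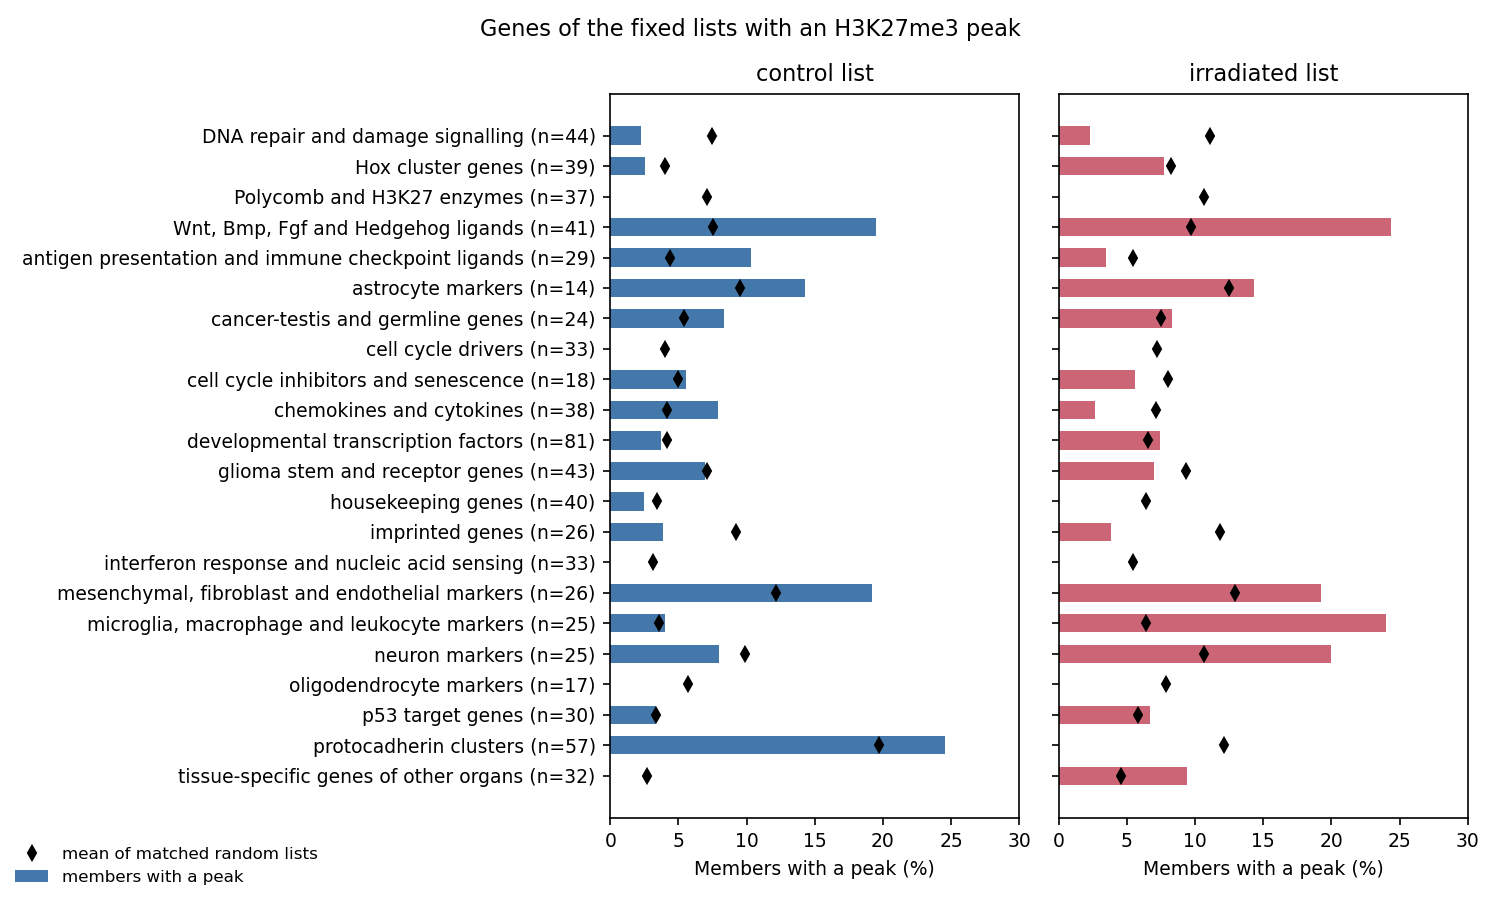
Share of the genes of each list fixed beforehand, in percent (horizontal axis), that had an H3K27me3 peak in the gene or within 2000 bp, in the control library (left) and the irradiated library (right). Bars are the observed shares, diamonds the mean of 10000 random lists matched on gene length and chromosome, and n the number of genes; Wnt, Bmp, Fgf and Hedgehog ligands lie above their diamond in both libraries.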

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

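The settings a q of at most 0.05, a −log10 p of at least 5, at least 12 reads, gene ends, matched random lists and peaks moved by up to 500 kb were chosen after seeing the data; the others were fixed beforehand. Of the values that answer a comparison, 89 moved beyond counting error or by over 1.5 times and 29 did not. The order of the lists turned with equal numbers of peaks for the genes of a single list, the share on chromosome 6 and the number of gene lists above the 95th percentile. The shares of shared peaks came out almost equal there, at 16.5% and 16.6%, which lists of equal length bring about by construction. The order turned for the shares on chromosomes 15 and 6 with a q of at most 0.05 and with a −log10 q of at least 5, and for that on chromosome 6 with a −log10 p of at least 5. Among single genes and lists 159 moved and 331 did not. Where the values moved, the cause was not tested, except where a stricter setting leaves fewer peaks or genes.

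With a −log10 q of at least 5 the irradiated list had 1.47 times as many peaks and 1.24 times the covered length, 68.1% of control and 48.0% of irradiated peaks were shared, and 11 coding genes were marked in both lists, 4 in the control list alone and 14 in the irradiated list alone. In gene regions lay 13.3% of control and 18.7% of irradiated peaks. Chromosomes 15, 11 and 6 held 1.48%, 1.48% and 2.96% of control peaks and 6.57%, 2.02% and 3.03% of irradiated peaks, and 0 control and 0 irradiated gene lists passed the 95th percentile. Set against all peaks of the other list, 92.6% of such control and 80.8% of such irradiated peaks were shared.

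With a q of at most 0.05 the peak ratio was 3.63, the ratio of covered length 3.42, and 40.3% of control and 11.5% of irradiated peaks were shared. The gene counts were 80 in both lists, 33 in the control list alone and 375 in the irradiated list alone, with 0 and 0 gene lists above the 95th percentile. In gene regions lay 24.0% and 34.1% of peaks. Chromosomes 15, 11 and 6 held 24.7%, 4.89% and 9.33% of control peaks, and chromosomes 15 and 11 held 25.1% and 12% of irradiated peaks. With a −log10 p of at least 5 the peak ratio was 4.03, the ratio of covered length 3.78, 34.1% of control and 8.84% of irradiated peaks were shared, and the genes were 129 in both lists, 59 in the control list alone and 588 in the irradiated list alone, with 0 and 0 gene lists above the 95th percentile. In gene regions lay 26.4% and 34.8% of peaks, and chromosomes 15, 11 and 6 held 28.2%, 6.48% and 10.8% of control and 21.7%, 12.3% and 13% of irradiated peaks. With at least 12 reads the ratios of peaks and of covered length were 3.37 and 3.33.

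With equal numbers of peaks the peak ratio is 1 by construction, the ratio of covered length was 1.11, 16.5% of control and 16.6% of irradiated peaks were shared, 680 genes were marked in both lists, 645 in the control list alone and 599 in the irradiated list alone, 36.7% of irradiated peaks lay in gene regions, 20.0% on chromosome 15 and 12.9% on chromosome 6, and 2 irradiated gene lists passed the 95th percentile. Merging peaks within 1000 bp gave ratios of 1.54 for regions and 1.79 for covered length; within 5000 bp they were 1.35 and 2.04, with 23.3% and 16.7% shared. An overlap of 50% of the shorter peak left 17.6% and 10.9% shared, a reciprocal overlap of 50% left 12% and 7.38%, and a distance of up to 1000 bp gave 31.9% and 21.5%. The excess over random placement was 7.78 times when peaks were moved by up to 500 kb.

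Gene windows of 500 bp held 30.1% of control and 36.3% of irradiated peaks, and windows of 5000 bp held 35.3% and 42.2%. Gene ends in place of whole genes gave 158 genes in both lists, 211 in the control list alone and 474 in the irradiated list alone, with 0 control and 1 irradiated gene list above the 95th percentile. Matched random lists left 1 and 2. Of the 10 genes the rule took for each class, 10 irradiated, 8 control and 10 shared ones kept their class at a q of at most 0.05 and with a window of 500 bp, 10, 10 and 10 at a −log10 p of at least 5, 8, 8 and 10 with a window of 5000 bp, 5, 4 and 3 with gene ends, and 0, 1 and 3 with a −log10 q of at least 5. The 2 irradiated and 2 control ones lost with the window of 5000 bp changed class, as did 3 shared ones under each of the last settings. Since the genes were taken for their low q, keeping their class at a q of at most 0.05 or a −log10 p of at least 5 followed from that choice. Stricter thresholds, the window of 500 bp and gene ends only remove peaks. They could not give a gene of a single list a peak in the other list. The lowest background from low-fold peaks came out at 3 scaled reads in the control list and 2 in the irradiated list; the peaks at the lowest background among them have 1 level of p, too few to fit it, so this setting says nothing of the background.

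No paired analysis was possible because each group had 1 library. Not run, for want of sequence or of transcription starts, were base composition and repeats of peaks (whole or around the summit), CpG-matched lists, and the most upstream start of each gene. Depth also limits the lists: a site with fewer than 7 control or 8 irradiated reads could not be called, and most calls lie within a few reads of that.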

Other observations

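Every comparison in this part was chosen after the data were seen. Gene families with a shared name and at least 15 members were compared with random genes matched on length and chromosome, and 6 of 153 lay above the 99th percentile in both lists. Keratin genes (Krt), the intermediate filaments of epithelia and hair, had 8 marked members of 53 in the control list and 19 in the irradiated list, against matched means of 2.59 and 6.55. Krt72, Krt73, Krt76 and Krt77 on chromosome 15 and Krt23, Krt26 and Krt33a on chromosome 11 were marked in both. Carboxylesterases of the liver (Ces) had 5 and 6 of 19, C-type lectins of immune cells (Clec) 8 and 9 of 33, protease inhibitors of the Wfdc family 4 and 7 of 18, and solute carriers (Slc) 39 and 51 of 375. The glucuronosyltransferases (Ugt), which conjugate drugs and bilirubin, had 11 of 22 in each list, but these rest on 3 strongest peaks because the Ugt1a genes overlap. Another 5 families lay above the 99th percentile in the control list but not in the irradiated list (Abca, Defb, Il, Olfr and Serpina) and 4 in the irradiated list but not in the control list (Cd, Cfap, Fam and Klk). Serpina genes, protease inhibitors of the liver, had 5 and 1 of 24, and leukocyte surface genes named Cd had 9 and 19 of 100. Below the 1st percentile lay 0 families in the control list and 6 in the irradiated list (Zfp, Vmn, Vps, Cep, Wdr and Map). These were zinc finger genes (Zfp), with 12 of 397 against a matched mean of 28.5, and vomeronasal receptors (Vmn), with 2 of 355 against 11.6, besides Vps with 0 of 35, Cep with 0 of 38, Wdr with 1 of 65 and Map with 1 of 47. In the control list Zfp and Vmn had 17 and 6, against 17.8 and 8.87. The difference between the lists was not tested for any family. Neighbouring genes of a family are not independent. Families were formed by name alone, and with 153 of them some would pass these percentiles in each list by chance. The lists also share many marked genes, so a family high in both does not rest on independent lists.

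The strongest peaks lay elsewhere than the rest. Of 135 control peaks with a q of at most 1e-05, 50 lay between 30 and 35 Mb of the X chromosome and 34 between 14 and 16 Mb of chromosome 5, where Spin2f and the Speer4 genes lie; of 198 irradiated peaks the numbers were 72 and 43. The input background was at least 1.5 times the lowest background in 75.6% of these control peaks (67.4 to 82.5) and 50.5% of these irradiated peaks (43.3 to 57.7), against 14.1% and 26.1% of the other peaks. In the first 45 Mb of chromosome 16 there were 243 control and 289 irradiated peaks, against 92 and 8 between 45 and 90 Mb.

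The irradiated list held 1.63 times as many peaks as the control list. The recovered ChIP reads per position were 0.858 times those of the control, which argues against a deeper irradiated library, and among peaks of at least 12 reads the ratio was 3.37 (3.21 to 3.54), which argues against a lower background letting weak sites pass. Reads per position also depend on the fragment length that the caller used, so they measure depth only roughly. A gain of a few chromosome segments would not give the excess beyond counting error seen on 16 of 19 autosomes. A more efficient immunoprecipitation stays open. The fold of shared peaks was 1.14 times the control fold, and the lowest fold called at the lowest background (3.19 against 2.78) also differs by 1.14 times. In 77 pairs with both q at most 1e-05 the ratio was 1.12, at median folds of 6.74 in the control and 7.89 in the irradiated list. These lie above the lowest folds of the whole lists, but a q of at most 1e-05 sets a higher limit of its own. Apol11a, at the lowest irradiated background, had a fold of 6.76 and a q of 1.47e-05, and so missed this threshold. The ratio of these pairs is thus not free of a calling limit. The lists were scaled separately, so the ratio does not decide. A base composition or fragmentation bias of the irradiated material, taken up below for gene-rich bins, stays open for the whole excess too. The ratio was 1.03 in gene-poor and 2.21 in gene-rich bins. With 1 library per group, neither a more efficient immunoprecipitation nor such a bias can be told apart from an effect of radiation, which was not tested.

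Peaks were concentrated on chromosomes 15, 11 and 6 in both libraries. The variance of peaks per 5 Mb bin was at least 12.2 times the mean on these chromosomes, but it reached 50.3 times on another autosome in the control list and 71.7 in the irradiated list, so this unevenness does not bear on a gain of whole chromosomes, which could be the only source or add to others. On chromosome 15, 44.7% of control peaks sat at the lowest input background against 50.5% outside these chromosomes, and 32.6% of irradiated peaks against 39.1%. The input is seen only where a peak was called, so this share cannot decide. The control cells were not irradiated, yet their list held 23.3% (22.5 to 24.2) of its peaks on chromosome 15. The irradiated list held 18.0% there. This argues against irradiation as the source of the concentration, with 1 library per condition. On chromosome 11 the share was 9.38% in the control and 13.5% in the irradiated list. Whether irradiation changed any of these shares was not tested.

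The irradiated excess was larger where genes are dense. The ratio of irradiated to control peaks was 1.03 (0.968 to 1.09) in the gene-poor part of 5 Mb bins, 1.43 in the middle part and 2.21 (2.12 to 2.29) in the gene-rich part, and it was higher in gene-rich than in gene-poor bins on 19 of 19 autosomes, which argues against a few chromosomes setting it. Among peaks of at least 12 reads the ratios were 4.74 (4.39 to 5.12) and 1.99 (1.77 to 2.24), a contrast of 2.38 times, which argues against weak calls. A base composition or fragmentation bias of the irradiated material may contribute: from gene-poor to gene-rich bins the share of peaks at the lowest input background fell by 17.6 percentage points in the irradiated list and fell by 6.69 in the control list, a difference of -10.9, but a bias of the ChIP library alone would not show there. An effect of irradiation itself was not tested, since that needs replicate libraries.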
